A study of Mus musculus with 6 samples.

How the data were processed

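Total RNA of mouse cells was sequenced in 6 libraries. Per the labels, 4 libraries came from primary leukemia cells of the Mll-Af4 and N-RasG12D model, 2 from leukemia 1 and 2 from leukemia 92. The other 2 came from wild-type pro-B cells of bone marrow, sorted as B220+ CD43+ IgM- cells. The model was made from c-Kit+ Sca1+ marrow cells of Mll-Af4 mice, which received a Cre retrovirus and an N-RasG12D retrovirus and were injected into irradiated mice together with wild-type helper marrow. RNA was taken with RNeasy kits and libraries with TruSeq RNA kits. The labels number 2 replicates in each group and do not say whether these are separate animals, so they may be technical, and a p from them then measures only that spread. The leukemia 1 libraries differed far more (SD of log2 differences 0.93, against 0.21 in the other pairs). This argues against repeats of 1 RNA sample for leukemia 1.

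The deposited table holds counts, whole-number reads per gene and library, with 33924 genes and 5 further entries that name no gene. STAR 2.4, HTSeq 0.6.1, DESeq2 and the mouse build mm9 are named per the submitters' processing notes, which give no role or order. The gene annotation and strand setting are not given in the sources used here, so genes are identified by the symbols of the table and positions are not printed. The entries that name no gene (reads not uniquely aligned, outside features or ambiguous) held 34.0% to 39.6% of the summed entries of a library and were left out. The entry for unaligned reads was 0 in every library, so unaligned reads are not part of these shares. Reads of the N-Ras retrovirus and of endogenous Nras are not told apart in such a table, nor are the fusion and the normal copies of Mll1 and Aff1.

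Gene counts summed to 22153444 to 27444759 per library, and 17960 to 19714 genes had at least 1 count. At this depth 3 counts in 1 library correspond to 0.111 to 0.140 CPM (counts scaled to library size). A fold against a group with no reads is computed from summed counts against a floor of 3 counts over all libraries of that group, scaled by their summed library sizes, and given as at least that fold. Where the lower group had 1 to 3 counts in all, the ratio is given with its 95% exact interval from the counts. Floors and intervals cover counting error alone.

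The comparison of leukemia with pro-B cells used the leukemia as the unit, because the labels place 2 libraries under each leukemia number. Counts were summed over the 2 libraries of each leukemia, and 2 leukemias were compared with 2 pro-B libraries. The comparison of leukemia 92 with leukemia 1 used all 6 libraries with 1 coefficient per group. Both used edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM normalisation, and the robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Adjusted p values of single genes are from these edgeR fits. The standard error (SE) of a log2 change was taken from its F statistic. CPM values are given as mean ± SD over libraries.

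A total of 21 gene lists was tested. They cover targets of MLL fusions, output and components of RAS to ERK signalling, the ATR and CHK1 checkpoint, homologous recombination and Fanconi genes, replication, mitosis, p53 targets, the BCL2 family, ribosome biogenesis, interferon response and immediate early and stress genes. The others hold markers of pro-B, mature B, plasma, stem and progenitor, myeloid, dendritic, T and NK, erythroid and platelet, and stromal and endothelial cells. Of 530 list entries 527 matched a symbol of the table, older synonyms included, and 3 erythroid entries did not. Lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 21 lists, with camera with an estimated correlation as an alternative. The fry test was run beside them and asks only whether the genes of a list move, on balance, in 1 direction.

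Named genes followed a rule: 10 genes of the model and its pathways, the 8 largest rises and 8 largest falls among called genes with all libraries on the same side and a mean of at least 20 CPM (predicted genes, immunoglobulin and receptor segments left out), and up to 2 called members of each list in each direction with the smallest p. For leukemia 92 against leukemia 1 the numbers were 6, 6 and 1. The rule gave 77 and 27 genes, of which 1 is not reported here. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined. Members of a list or family outside the rule are named in the text as examples chosen after their values were seen.

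The whole pipeline was tested on simulated data with known changes. For leukemia against pro-B cells, with 14829 genes simulated, 1.05% of 2-fold changes and 49.5% of 4-fold changes were recovered, and 13 unchanged genes were called. For leukemia 92 against leukemia 1, with 14554 genes simulated, 0% and 22.2% were recovered, and 1 unchanged gene was called. A shifted mitosis list was recovered in both, and of the 20 other lists 0 and 1 were called, respectively. Genes were drawn independently of each other in the simulation. It therefore cannot show how often lists of correlated genes are called falsely. In these simulations, where few genes were changed, 2-fold changes in single genes were mostly missed. In the real data 20.2% of genes were called for leukemia against pro-B cells, some of them with changes below 2-fold. The adjustment was less strict there, so these recovery rates do not carry over directly.

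The alternatives were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, glmTreat against a fold of 1.5, removal of immunoglobulin and haemoglobin genes, each library as a replicate with and without a replicate block, a 3-group fit, the leukemia libraries alone, and leaving out each library or each leukemia. Where a group was left with 1 sample, its spread was taken from the other groups. With 1 leukemia left, the spread came from the 2 pro-B libraries alone. Calls gained or lost there do not measure variation between leukemias.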

Results

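Expression was measured by RNA sequencing in 3 groups of 2 libraries each: leukemia 1, leukemia 92 and wild-type pro-B cells. Leukemia 1 had 25912299 and 27444759 gene counts in replicates 1 and 2, leukemia 92 had 25381643 and 22153444, and the pro-B libraries had 25030842 and 24026378. The 10 most abundant genes held 3.61% to 5.51% of the counts of a library. On the first principal component, which carried 69.4% of the variance, all 4 leukemia libraries lay apart from both pro-B libraries. The SD of log2 differences between replicates was 0.21 for leukemia 92 and 0.21 for pro-B cells. For leukemia 1 it was 0.93, larger than the 0.77 to 0.83 between libraries of the different leukemias. Replicate 2 of leukemia 1 carried far more granulocyte transcripts than replicate 1: S100a8 stood at 3613 against 45.0 CPM, S100a9 at 5456 against 63.6 CPM and Mpo at 332 against 2.60 CPM. Its Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) also summed to 1205 counts against 121 in replicate 1, 0 and 6 in leukemia 92 and 0 in both pro-B libraries.

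The main comparison asks how the leukemia, driven by an Mll-Af4 fusion and activated N-Ras, differs from the normal pro-B cell. Nras, the small GTPase of the model's second hit, stood at 445 ± 102 CPM in leukemia (SD, n = 4 libraries) and 156 ± 0.612 CPM in pro-B cells (SD, n = 2), a rise of 1.52 on the log2 scale (SE 0.26, edgeR adjusted p = 0.032). Etv4, a transcription factor induced by ERK signalling, rose from 0.305 ± 0.0649 to 67.8 ± 9.59 CPM (log2 change 7.80, SE 0.22, adjusted p = 0.0065). Dusp6, the ERK phosphatase, rose from 140 ± 0.483 to 508 ± 55.7 CPM (log2 change 1.87, SE 0.11, adjusted p = 0.0083). Hoxa9, a known target of MLL fusion proteins, fell from 6.69 ± 0.0783 to 0.478 ± 0.375 CPM (log2 change -3.78, SE 0.43, adjusted p = 0.017). The pro-B transcript Pax5 (132 ± 9.39 against 97.6 ± 1.04 CPM, adjusted p = 0.062) did not pass the test. Its log2 change was 0.40 for leukemia 92 alone and 0.45 for leukemia 1 alone, fits whose spread comes from the pro-B pair only.

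Of 15280 genes tested, 1458 rose and 1631 fell in leukemia, 1139 and 1405 of them by at least 2-fold, and 5922 had an unadjusted p under 0.05. Without leukemia 1 replicate 2 the numbers were 993 and 1725, so the share of rises among called genes was 36.5% against 47.2% with all libraries. The numbers without leukemia 1 replicate 1 were 935 and 1022. With 1 pro-B library left out edgeR called 0 genes, for replicate 1 and for replicate 2, with 2645 and 2650 genes at an unadjusted p under 0.05, and no called gene changed sign. Without both libraries of leukemia 1, or both of leukemia 92, 1 summed leukemia sample was left. The spread then came from the 2 pro-B libraries alone, so the number of calls is not comparable. Camera called 7 of the 21 lists higher and 8 lower. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry called 4 higher and 4 lower.

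ERK output genes were higher as a list: of 18 tested, 10 rose, 1 fell and 7 did not pass, and 11 and 1 passed adjusted over the list alone. The median log2 change was 1.93 (camera adjusted p = 2.8e-06), with adjusted p = 0.41 with an estimated correlation. Phlda1 rose from 7.78 ± 0.526 to 118 ± 13.7 CPM. Spry4 (log2 change 4.73), Dusp4 (3.88) and Spred1 (2.79), feedback inhibitors chosen after their values were seen, rose too. Spry2, another feedback inhibitor, fell by 1.11 on the log2 scale (SE 0.23, adjusted p = 0.046, and 0.18 without leukemia 1 replicate 1). Components of the pathway itself did not shift as a list (median log2 change 0.13, camera adjusted p = 0.29): of 23 tested, 2 rose, 1 fell and 20 did not pass, and 1 and 1 passed adjusted over the list alone. These were Nras, Rasgrp2 (0.73) and Rasgrp1, a RAS exchange factor, which fell from 46.4 ± 5.99 to 1.35 ± 1.36 CPM (log2 change -5.06, and -6.20 without leukemia 1 replicate 2). The adjusted p of Rasgrp2 was 0.042, against 0.056 and 0.13 without leukemia 1 replicates 1 and 2.

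Immediate early and stress genes were higher as well, with 11 of 24 called higher and 13 not passing, 15 higher and 1 lower adjusted over the list alone. Immediate early genes had a median log2 change of 1.38 (camera adjusted p = 2.8e-06), with adjusted p = 0.32 with an estimated correlation. Egr1, an early growth response factor downstream of ERK, rose from 70.5 ± 2.67 to 656 ± 204 CPM. Klf2 rose by 2.22 on the log2 scale (SE 0.14, adjusted p = 0.0087), against 1.502 with an adjusted p of 0.32 without leukemia 1 replicate 2. That library had 338 CPM of Klf2, while leukemia 1 replicate 1 had 35.0 CPM, below the 40.2 and 45.8 CPM of the pro-B libraries.

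Targets of p53 rose in 11 of 24 cases (7 without leukemia 1 replicate 1), with 1 fall (2 without leukemia 1 replicate 2 or leukemia 92 replicate 1) and 12 that did not pass, and 14 and 2 passed adjusted over the list alone. The median log2 change was 0.92 (camera adjusted p = 1.2e-04), with adjusted p = 0.32 with an estimated correlation. Zmat3 rose from 9.24 ± 0.445 to 203 ± 56.4 CPM (log2 change 4.47, SE 0.27) and Phlda3 from 1.83 ± 0.282 to 32.6 ± 8.61 CPM (log2 change 4.15, SE 0.27). Cdkn1a, the cell cycle inhibitor p21 (log2 change 3.68, chosen after its value was seen), rose too, while Rrm2b, a ribonucleotide reductase subunit, fell by 1.71 on the log2 scale. The BCL2 family shifted in the same direction, with 11 of 16 higher and 5 not passing, and 11 higher adjusted over the list alone. Its median log2 change was 1.42 (camera adjusted p = 2.8e-06), with adjusted p = 0.32 with an estimated correlation. Members on both sides of apoptosis were among them: the survival genes Mcl1 (490 ± 22.5 to 1128 ± 194 CPM) and Bcl2a1d (log2 change 7.47), and the death genes Bbc3 (3.44), Pmaip1 (3.92) and Bcl2l11 (1.73), the last 3 chosen after their values were seen. Bbc3, Pmaip1 and Bax stand in both lists, and reads of the Bcl2a1 paralogs cannot be assigned with certainty.

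MLL fusion targets moved both ways: of 23 tested, 5 rose (2 without leukemia 1 replicate 1), 11 fell and 7 did not pass, and 8 and 12 passed adjusted over the list alone. The median log2 change was -1.62 (camera adjusted p = 0.041), with adjusted p = 0.71 with an estimated correlation. The preset call was also lost without leukemia 1 replicate 2 (adjusted p = 0.12), without leukemia 92 replicate 1 (adjusted p = 0.055) and without both libraries of leukemia 1 (adjusted p = 0.33). Mef2c, a transcription factor of lymphoid progenitors, rose from 273 ± 16.2 to 992 ± 450 CPM (log2 change 1.85), and the demethylase-family gene Jmjd1c from 229 ± 18.0 to 520 ± 232 CPM (log2 change 1.17). Without leukemia 1 replicate 1 these changes were 1.42 and 0.75, with adjusted p values of 0.084 and 0.28. Zfp521 fell by 7.60 on the log2 scale (a change of -8.63 without leukemia 1 replicate 2). Tcf4, whose change of -1.62 is also the median of the list, and Runx2 (-2.93, chosen after its value was seen) fell and are in the dendritic cell list too, which was lower in the same libraries. Hoxa9 had an adjusted p of 0.12 without leukemia 1 replicate 2. Meis1, its partner, was at 2.28 ± 2.08 against 9.27 ± 0.0698 CPM and did not pass (adjusted p = 0.23). Its log2 change was -1.17 for leukemia 92 alone and -4.03 for leukemia 1 alone. Reads of Mll1, which the fusion shares with the normal gene, fell from 257 ± 8.02 to 108 ± 30.8 CPM (log2 change -1.24, adjusted p = 0.033, and 0.088 without leukemia 1 replicate 1). Aff1 was at 179 ± 45.2 against 245 ± 16.1 CPM (log2 change -0.45, adjusted p = 0.079). The log2 change of Aff1 was -0.42 for leukemia 92 alone and -0.51 for leukemia 1 alone.

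Mitotic genes were lower, with 11 of 30 called lower and 19 not passing, and 21 lower adjusted over the list alone. In place of 11, the number called lower was 1 without leukemia 1 replicate 1, 23 without its replicate 2 and 7 without leukemia 92 replicate 2. Mitotic genes had a median log2 change of -0.99 (camera adjusted p = 4.7e-08), with adjusted p = 0.60 with an estimated correlation. Plk1, the mitotic kinase, fell from 71.7 ± 1.70 to 31.8 ± 13.7 CPM and the kinesin Kif20a from 103 ± 0.254 to 50.6 ± 8.82 CPM, with adjusted p values of 0.020 and 0.023 that became 0.16 and 0.067 without leukemia 1 replicate 1. Replication genes were lower as a list (median log2 change -0.43, camera adjusted p = 0.0041), with adjusted p = 0.76 with an estimated correlation. Of 32 tested, 31 did not pass and 1 fell (2 without leukemia 1 replicate 2), also adjusted over the list alone: Pold1, a catalytic subunit of DNA polymerase delta, from 146 ± 5.10 to 60.1 ± 9.47 CPM (log2 change -1.26, SE 0.11). Without both libraries of leukemia 92 the adjusted p of the list was 0.39.

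The series concerns inhibition of MEK and ATR, and no treated cells are among these libraries. Atr, the kinase of the replication stress checkpoint, fell from 102 ± 0.625 to 64.5 ± 9.90 CPM (log2 change -0.66, SE 0.12, adjusted p = 0.034, and 0.11 without leukemia 1 replicate 2). Chek1, its effector kinase, was at 46.8 ± 23.0 against 65.9 ± 2.51 CPM (log2 change -0.51, adjusted p = 0.37). The log2 change of Chek1 was -1.11 for leukemia 92 alone, a fit whose spread comes from the pro-B pair only. In the ATR and CHK1 list 2 of 20 genes fell, Atr and the transcript 4933413G19Rik (log2 change -2.74), which lost its call without leukemia 1 replicate 1 (adjusted p = 0.10) and without leukemia 92 replicate 1 (adjusted p = 0.060). With edgeR 0 passed adjusted over the list alone, 3 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 3 lower. The median log2 change was -0.40 (camera adjusted p = 0.23, and 0.042 without leukemia 1 replicate 1), and it was -0.61 without both libraries of leukemia 1. Among homologous recombination and Fanconi genes 3 of 30 fell (1 without leukemia 1 replicate 2), 2 of them adjusted over the list alone, and 27 did not pass. The median log2 change was -0.26 (camera adjusted p = 0.11, and 0.018 without leukemia 1 replicate 1). Fancd2 fell by 1.03 on the log2 scale (SE 0.15). Atm, the kinase of the double-strand break response, fell by 0.80 (SE 0.11, adjusted p = 0.023, against 0.067 and 0.099 without leukemia 1 replicates 1 and 2). Ribosome biogenesis genes were slightly higher (median log2 change 0.26, camera adjusted p = 0.010), with adjusted p = 0.71 with an estimated correlation. Of 29 tested, 4 rose (1 without leukemia 1 replicate 1) and 25 did not pass, with 1 higher adjusted over the list alone. Ppan rose from 41.0 ± 0.853 to 84.4 ± 14.2 CPM, and Pes1 from 110 ± 3.71 to 169 ± 14.7 CPM, with adjusted p = 0.073 for Pes1 without leukemia 1 replicate 1. The call of the ribosome list was lost without pro-B replicate 1 (adjusted p = 0.096) or replicate 2 (adjusted p = 0.16), and without both libraries of leukemia 1 (adjusted p = 0.49).

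Pro-B identity genes split. Of 33 tested, 3 rose, 11 fell and 19 did not pass, and 4 and 14 passed adjusted over the list alone. The median log2 change was -0.46 (camera adjusted p = 0.0053), with adjusted p = 0.41 with an estimated correlation. Cd79a, a chain of the B-cell receptor complex, rose from 432 ± 26.8 to 1295 ± 204 CPM and Vpreb3 from 327 ± 20.3 to 840 ± 240 CPM (adjusted p = 0.020, and 0.0503 without leukemia 1 replicate 1). Dntt, the terminal transferase of V(D)J joining, fell from 787 ± 259 to 0.349 ± 0.518 CPM (log2 change -11.05, SE 1.23, and -12.81 without leukemia 1 replicate 2), with adjusted p = 0.054 without both libraries of leukemia 92. Blk, a B-lineage kinase, fell from 164 ± 22.9 to 4.38 ± 1.74 CPM. Bst1 fell by 3.34 on the log2 scale (adjusted p = 0.014, and 0.054 without leukemia 1 replicate 1), with a change of -4.18 without replicate 2. Markers of mature B cells were higher, with 5 of 22 called higher, 1 lower and 16 not passing, and 7 and 1 adjusted over the list alone. Their median log2 change was 0.87 (camera adjusted p = 0.0034), with adjusted p = 0.51 with an estimated correlation. The activation markers Cd83 (1.74 ± 0.843 to 147 ± 53.6 CPM) and Cd86 (3.84 ± 1.13 to 57.0 ± 27.3 CPM) rose, and the transcription factor Spib fell by 2.84 on the log2 scale. Plasma cell genes gave no call as a list (median log2 change -0.55, camera adjusted p = 0.29). The median was -1.06 without both libraries of leukemia 1. Of 12 tested, 1 rose, 3 fell (5 without leukemia 1 replicate 2) and 8 did not pass, the same numbers as adjusted over the list alone. Edem1 rose by 1.91, Creb3l2 fell by 1.06, and Sdc1, the plasma cell antigen CD138, fell by 3.31 on the log2 scale (adjusted p = 0.034, and 0.093 without leukemia 1 replicate 1), with a change of -4.01 without replicate 2. Interferon response genes were lower, with 1 of 30 higher, 7 lower (3 without leukemia 1 replicate 1) and 22 not passing, and 2 and 8 adjusted over the list alone. Their median log2 change was -0.67 (camera adjusted p = 0.030), with adjusted p = 0.41 with an estimated correlation. The call was lost without leukemia 1 replicate 1 (adjusted p = 0.21) or leukemia 92 replicate 2 (adjusted p = 0.080) and in the 3-group fit (adjusted p = 0.077). Irf7 fell by 2.62 on the log2 scale, with a change of -3.29 and adjusted p = 0.074 without leukemia 1 replicate 2. Bst2, which is also in the dendritic cell list, fell by 2.63, and dendritic cell markers such as Ccr9 were lower in the same libraries. Oas2 rose by 2.48, against 3.05 (adjusted p = 0.051) and 1.49 (adjusted p = 0.29) without leukemia 1 replicates 1 and 2.

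**Figure D1:**
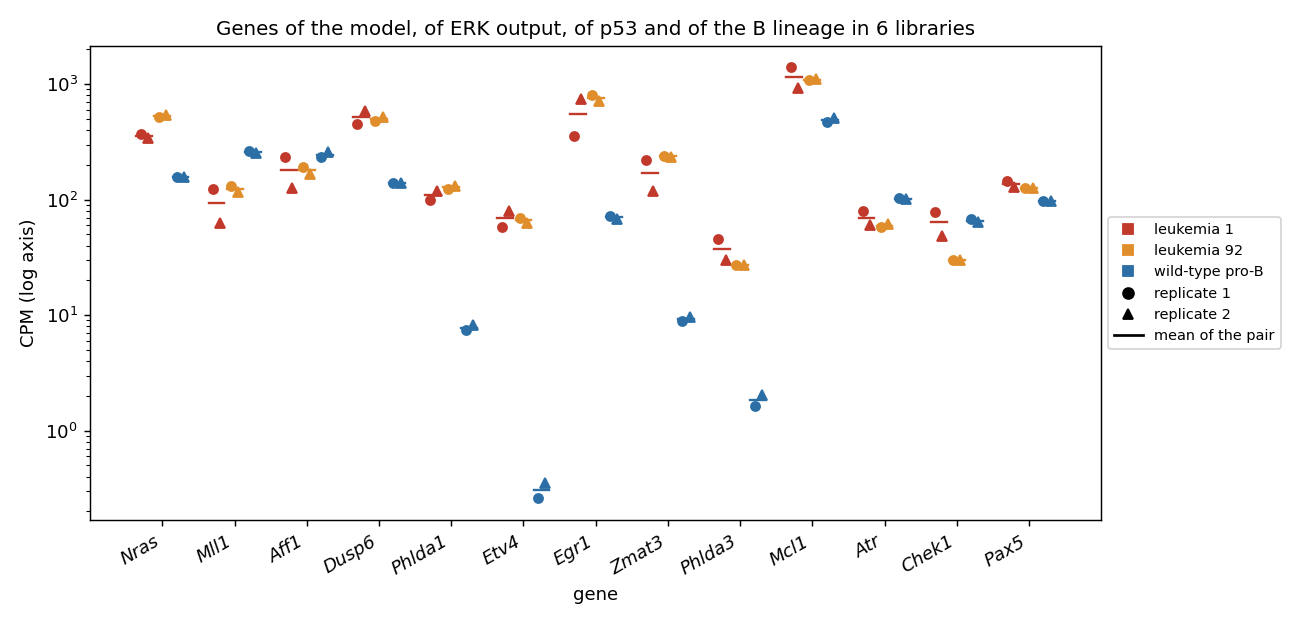
Expression in CPM on a log axis for named genes of the main comparison, 1 point per library with the groups in separate colours and a bar at each group's mean. Etv4 has means of 69.2 CPM in leukemia 1, 66.5 CPM in leukemia 92 and 0.305 CPM in pro-B cells, and Nras of 357, 532 and 156 CPM.

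Markers of other cell types differed strongly, in both directions. Myeloid genes were higher in leukemia: 9 of 34 rose and 25 did not pass, and 11 rose adjusted over the list alone. Myeloid genes had a median log2 change of 3.37 (camera adjusted p = 3.8e-06), with adjusted p = 0.50 with an estimated correlation. That call was lost without leukemia 1 replicate 2, the library with granulocyte transcripts, where the median was 0.32, 2 rose, 2 fell and the adjusted p was 0.31. With the replicate block the median was 1.97 with adjusted p = 7.9e-04. Cebpb rose from 1.33 ± 0.102 to 20.0 ± 1.91 CPM and was alike in all 4 leukemia libraries (18.8 to 22.9 CPM). Mmp9 rose by 5.28 on the log2 scale, against 4.16 (adjusted p = 0.12) without that library, and stood at 178 and 133 CPM in leukemia 92 and 4.87 ± 0.178 CPM in pro-B cells. T and NK cell genes were lower, with 11 of 28 called lower and 17 not passing, and 1 higher and 14 lower adjusted over the list alone. T and NK genes had a median log2 change of -3.25 (camera adjusted p = 4.7e-09), with adjusted p = 0.41 with an estimated correlation. Gzma, a granzyme of cytotoxic cells, fell from 97.6 ± 10.1 to 0.454 ± 0.501 CPM (log2 change -7.74, and -8.49 without leukemia 1 replicate 2) and the NK receptor Klrk1 from 64.4 ± 0.363 to 2.66 ± 1.65 CPM. Without leukemia 1 replicate 2, 22 of the T and NK genes fell (median -5.06), and without replicate 1, 6 fell. Dendritic cell genes were lower, with 2 of 21 higher, 9 lower and 10 not passing, and 2 and 11 adjusted over the list alone. Their median log2 change was -1.67 (camera adjusted p = 2.8e-04), with adjusted p = 0.41 with an estimated correlation. Ccr9, a marker of plasmacytoid dendritic cells, fell from 158 ± 28.2 to 1.03 ± 0.725 CPM. Zbtb46, a factor of classical dendritic cells, rose from 0.591 ± 0.102 to 40.4 ± 26.7 CPM and the integrin Itgax from 157 ± 20.0 to 517 ± 125 CPM.

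Erythroid and platelet genes were lower, with 13 of 21 called lower (7 without leukemia 1 replicate 1) and 8 not passing, and 1 higher and 16 lower adjusted over the list alone. Erythroid genes had a median log2 change of -4.82 (camera adjusted p = 6.8e-06), with adjusted p = 0.60 with an estimated correlation. Hbb-b2, a globin whose reads may be shared with its paralogs, fell from 19.9 ± 9.78 to 0.569 ± 0.130 CPM, and Alas2, of haem synthesis, from 10.6 ± 6.51 to 0.369 ± 0.0456 CPM. Both lost their call in a single leukemia, with adjusted p = 0.068 and 0.096 without leukemia 1 and 0.086 and 0.11 without leukemia 92. The 2 pro-B libraries differed here, with Hbb-b1 at 36.5 and 82.2 CPM. Stem and progenitor genes did not shift (median log2 change 0.06, mean -0.17, test downward with camera adjusted p = 0.77): of 19 tested, 3 rose, 3 fell and 13 did not pass, and 3 and 4 passed adjusted over the list alone. Without leukemia 1 replicate 1 or 2 the median was -0.15 or -0.67. Tal1 rose by 2.57 and Ptch1 fell by 1.20 on the log2 scale. Stromal and endothelial genes had a median of 1.36, a mean of -0.09 and a downward test (camera adjusted p = 0.60), with 1 of 13 higher, 3 lower (5 without leukemia 1 replicate 2) and 9 not passing, and 2 and 5 adjusted over the list alone. The stromal median was -1.78 without leukemia 1 replicate 2. Cdh5, the endothelial cadherin, fell from 31.2 ± 2.21 to 1.92 ± 0.219 CPM and Kdr by 4.53 on the log2 scale (a change of -5.34 without leukemia 1 replicate 2). Pecam1 rose by 1.45, with adjusted p = 0.070 without leukemia 1 replicate 1.

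**Figure D2:**
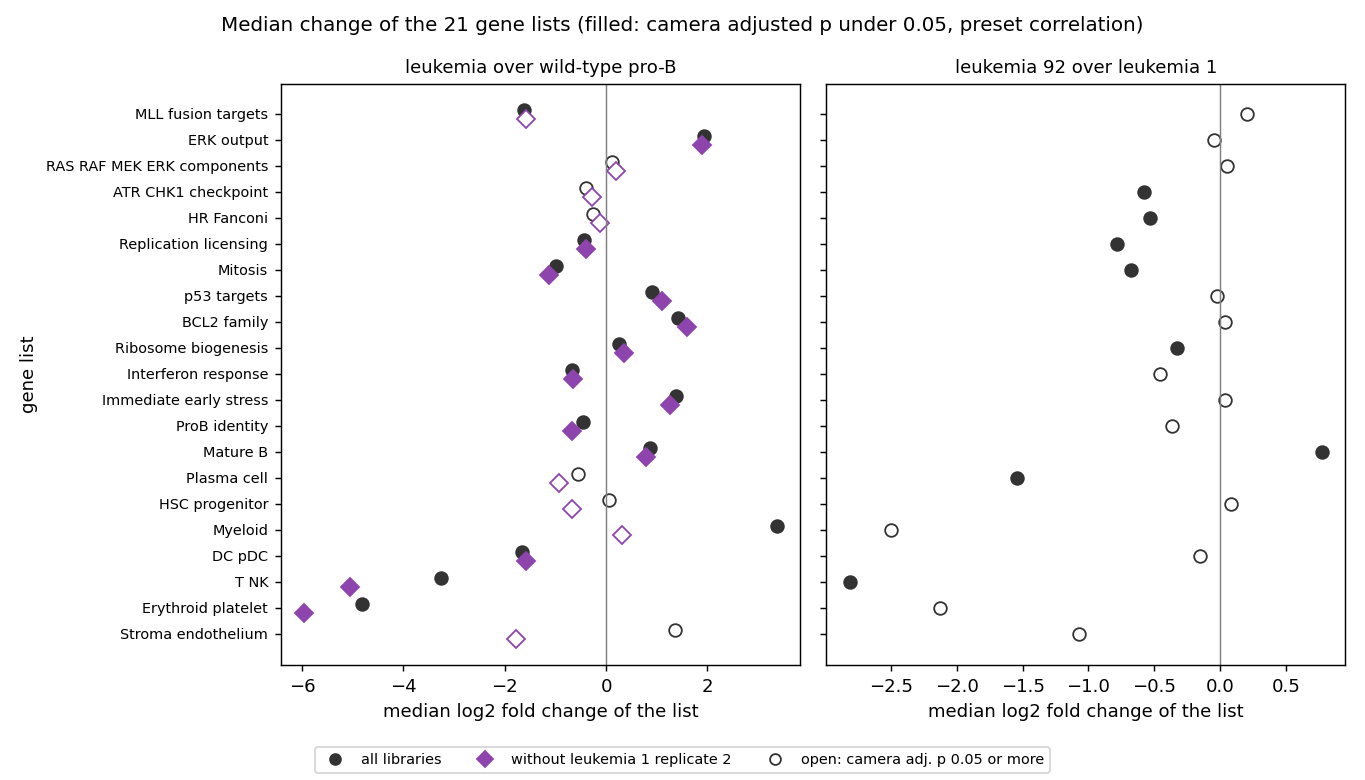
Median log2 change of each gene list for leukemia over pro-B cells (left, with and without leukemia 1 replicate 2) and leukemia 92 over leukemia 1 (right), filled where camera with the preset correlation gave an adjusted p under 0.05. The myeloid median moves from 3.37 to 0.32 without that library, while ERK output genes have a median of 1.93 with all libraries.

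Among the largest rises were genes with no reads in pro-B cells: Ntrk2, a neurotrophin receptor, was at least 575-fold higher, Cdkn2b, the cell cycle inhibitor p15, at least 388-fold, and the stefins Stfa1 and Stfa2 at least 411-fold and 553-fold. Otogl was higher by a ratio of 4778 (95% interval 1635 to 23172), Stfa3 by 1971 (354 to 77872) and Npr3 by 1850 (633 to 8971). Cdh17, a cadherin, rose from 0.479 ± 0.206 to 896 ± 294 CPM (log2 change 10.88, SE 0.54, adjusted p = 0.0074). Reads of the stefin paralogs cannot be assigned with certainty, and the calls of Stfa1 and Stfa2 were at the margin. The adjusted p of Stfa2 was 0.049, against 0.0503, 0.074 and 0.055 without leukemia 1 replicate 1, leukemia 1 replicate 2 and leukemia 92 replicate 2, and that of Stfa1 was 0.042, against 0.055 without leukemia 1 replicate 2. Ntrk2 was at 45.8, 32.9 and 58.2 CPM in 3 leukemia libraries and at 0.666 CPM in leukemia 1 replicate 2, and had an adjusted p of 0.019, against 0.16 without leukemia 1 replicate 1.

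The largest falls included 2 receptors of the Ly49 family of NK cells, Klra4 with a ratio of 6051 (95% interval 1085 to 239062) and Klra8 with 1123 (310 to 9282), which also share reads with paralogs. Klk1, expressed in plasmacytoid dendritic cells, was lower by a ratio of 5487 (984 to 216778), Smtnl2 by 1670 (571 to 8102) and Grm8 by 1130 (312 to 9343). Cacna2d1, a calcium channel subunit, fell from 57.7 ± 11.2 to 0.0419 ± 0.0490 CPM and Fcrl6 from 42.7 ± 14.2 to 0.0443 ± 0.0663 CPM. These falls stand beside the lower T, NK and dendritic markers of the leukemia libraries. The test had 2 residual degrees of freedom, and because the leukemia libraries came from primary disease and the pro-B cells from a marrow sort, the disease and the source of the cells differ together.

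**Figure D3:**
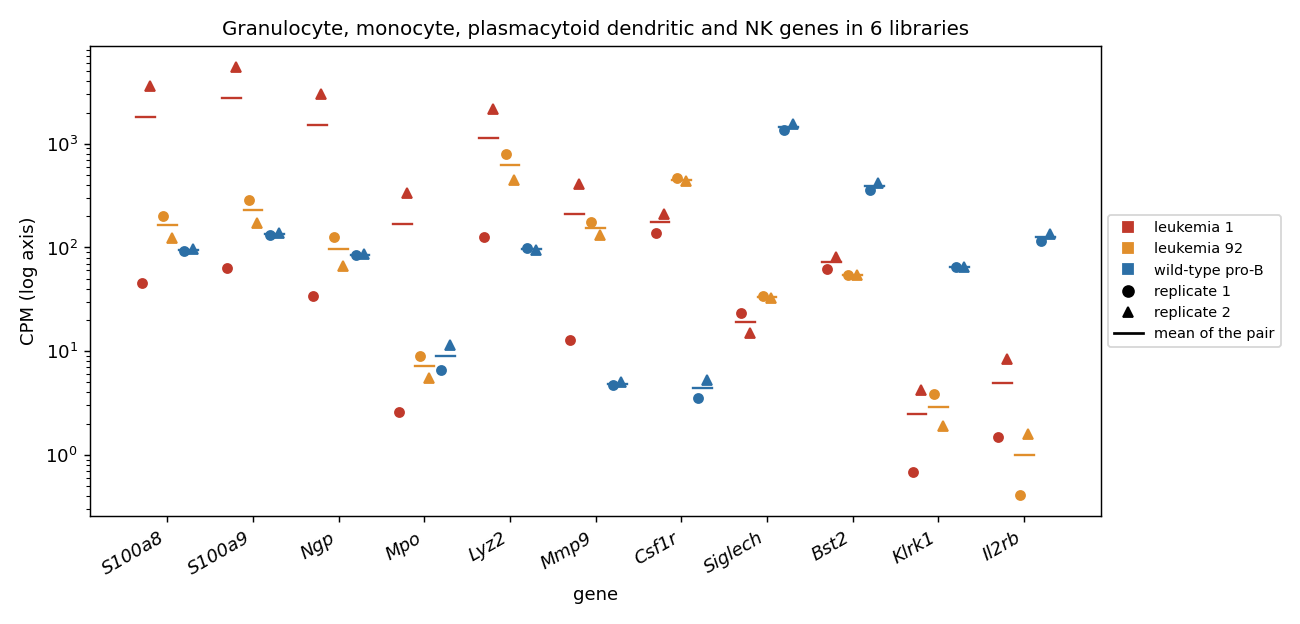
Expression in CPM on a log axis of granulocyte, monocyte, plasmacytoid dendritic and NK cell genes in each of the 6 libraries, with a bar at the mean of each pair. S100a8 stands at 3613 CPM in leukemia 1 replicate 2 and 45.0 CPM in replicate 1, and Klrk1 at 64.6 and 64.1 CPM in the pro-B libraries.

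The other comparison asks how the 2 leukemias differ from each other. Leukemia 92 carried 1251 ± 65.8 CPM of Brip1, a helicase of DNA crosslink repair, against 38.5 ± 15.4 CPM in leukemia 1 and 46.6 ± 2.01 CPM in pro-B cells (SD, n = 2 each), a rise of 5.02 on the log2 scale (SE 0.34, edgeR adjusted p = 0.023). Cd22, a B-cell lectin, stood at 304 ± 22.4 against 70.4 ± 1.44 CPM (log2 change 2.11, SE 0.14, adjusted p = 0.023). H19, an imprinted RNA, fell from 184 ± 90.7 CPM in leukemia 1 to 5.06 ± 0.811 CPM in leukemia 92 (log2 change -5.19, SE 0.49, adjusted p = 0.027, and -4.56 without leukemia 1 replicate 2). Replication and mitosis genes were lower in leukemia 92, with median log2 changes of -0.78 and -0.68, calls that were lost with adjusted p = 0.35 and adjusted p = 0.56 with an estimated correlation. Both leukemias share the pro-B libraries, so these are also the differences between their changes from pro-B cells.

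Of 14979 genes tested, 273 were higher in leukemia 92 and 190 lower, 225 and 142 of them by at least 2-fold, and 3759 had an unadjusted p under 0.05. These counts depend on which pairs of libraries set the spread. Without leukemia 1 replicate 1 or replicate 2, that group held 1 library. The spread then came from the leukemia 92 and pro-B pairs, so the number of calls is not comparable. Without leukemia 92 replicate 1 or 2, or pro-B replicate 1 or 2, edgeR called 0 genes, with 1552, 1704, 2301 and 2303 at an unadjusted p under 0.05, and no called gene changed sign. Because the replicates may come from the same animal, the p measures the spread between libraries within groups and says nothing about other leukemias. That spread is pooled over the pairs of leukemia 1, leukemia 92 and pro-B cells (SD of log2 differences 0.93, 0.21 and 0.21). The pro-B pair therefore contributes to it without being part of the comparison. On the leukemia libraries alone, with fewer residual degrees of freedom, edgeR called 0 genes, with 2366 at an unadjusted p under 0.05.

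Replication genes had the smallest camera p: of 32 tested, 7 fell and 25 did not pass, and 29 fell adjusted over the list alone. Camera gave adjusted p = 1.0e-15, with adjusted p = 0.35 with an estimated correlation. Rfc3, of the clamp loader, fell from 94.3 ± 1.73 to 49.6 ± 3.50 CPM (log2 change -0.93, SE 0.12), and Pcna (-0.86) and Mcm6 (-0.83), chosen after their values were seen, fell too. In the mitosis list 9 of 30 fell and 21 did not pass, 17 adjusted over the list alone (camera adjusted p = 4.1e-12), with adjusted p = 0.56 with an estimated correlation. Bub1b, of the spindle checkpoint, fell from 217 ± 9.16 to 103 ± 6.12 CPM. ATR and CHK1 checkpoint genes had a median log2 change of -0.57 (camera adjusted p = 0.0011), with adjusted p = 0.56 with an estimated correlation, and 0.12 without leukemia 1 replicate 1. Of 20 tested, 1 fell and 19 did not pass, with 1 higher and 5 lower adjusted over the list alone. Rpa2, of the single-strand binding complex, fell by 0.81 on the log2 scale. Homologous recombination and Fanconi genes had a median of -0.53 (camera adjusted p = 5.6e-04), with adjusted p = 0.56 with an estimated correlation, and 0.48 without leukemia 1 replicate 1. Of 30 tested, 1 rose (Brip1), 3 fell and 26 did not pass, with 1 and 5 adjusted over the list alone. Bard1, the partner of Brca1, fell by 1.28 on the log2 scale. Ribosome biogenesis genes had a median of -0.33 (camera adjusted p = 0.0014), with adjusted p = 0.59 with an estimated correlation, and 0.30 without leukemia 1 replicate 1. Of its 29 genes edgeR called 0, also adjusted over the list alone, with 9 lower at an unadjusted p under 0.05 and 6 lower by DESeq2.

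Mature B genes were higher in leukemia 92 (median 0.78, camera adjusted p = 5.6e-04), with adjusted p = 0.35 with an estimated correlation. Of 22 tested, 3 rose and 19 did not pass, with 8 higher and 2 lower adjusted over the list alone. Ltb, lymphotoxin beta, rose from 8.93 ± 0.131 to 31.4 ± 2.10 CPM. Pro-B identity genes went both ways, with 3 of 33 higher, 2 lower and 28 not passing, 4 and 7 adjusted over the list alone (median -0.36, camera adjusted p = 0.28). Rag2, of the V(D)J recombinase, fell by 1.84 on the log2 scale. Plasma cell genes had a median of -1.54 (camera adjusted p = 0.013), with adjusted p = 0.49 with an estimated correlation. The plasma cell median was -0.36 (adjusted p = 0.0047) without leukemia 1 replicate 2, a library with 107 CPM of Igj against 0.285 CPM in replicate 1. Of 12 tested, 1 fell, also adjusted over the list alone, and 11 did not pass: Xbp1, a regulator of the secretory programme, fell from 237 ± 19.4 to 127 ± 2.32 CPM. The T and NK list had a median of -2.81 (camera adjusted p = 0.0084), or -2.62 with genes at 0 placed at the floor, with adjusted p = 0.77 with an estimated correlation. Yet of its 28 genes 2 rose and 26 did not pass, with 3 higher and 1 lower adjusted over the list alone, and the risers were Klrd1 (2.95, and 3.64 without leukemia 1 replicate 2) and Cd5 (1.64, chosen after its value was seen). The T and NK median was -0.70 with adjusted p = 0.95 without leukemia 1 replicate 2, and the adjusted p was 0.30 on the leukemia libraries alone.

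Myeloid genes were not called (median -2.50, camera adjusted p = 0.82): edgeR called 0 of 34, with 5 higher at an unadjusted p under 0.05, 4 higher adjusted over the list alone, and 5 higher and 5 lower by DESeq2. Leukemia 1 replicate 2 sets this median, and without it the median was 1.70, with 22 genes higher and adjusted p = 2.1e-09, while without replicate 1 it was -3.32 with adjusted p = 6.9e-10. Erythroid and platelet genes had a median of -2.13, or -0.62 with genes at 0 placed at the floor (camera adjusted p = 0.11). Of 20 tested edgeR called 0, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2. The adjusted p of the erythroid list was 0.039, 0.017 and 0.029 without leukemia 92 replicate 1, pro-B replicate 1 and pro-B replicate 2, 0.029 with the replicate block and 0.031 without a filter on low counts. Dendritic cell genes had 1 of 20 higher and 19 not passing, 2 higher adjusted over the list alone (median -0.15, mean -0.27, test upward, camera adjusted p = 0.46, median 0.45 and 0.59 without leukemia 1 replicates 1 and 2). Zbtb46 rose from 17.7 ± 3.62 to 63.0 ± 8.31 CPM. Stromal and endothelial genes had 1 of 11 higher and 10 not passing, 3 higher adjusted over the list alone (median -1.07, or -0.49 with genes at 0 at the floor, mean -1.20, test upward, camera adjusted p = 0.51, median 1.95 without leukemia 1 replicate 2). Pdgfrb rose by 3.01 on the log2 scale. Of 18 stem and progenitor genes edgeR called 0, also adjusted over the list alone, with 3 higher and 2 lower at an unadjusted p under 0.05 and 2 and 3 by DESeq2. Their median was 0.08, their mean -0.48 and the test upward (camera adjusted p = 0.59), and the median lay between -0.17 and -0.06 without leukemia 1 replicate 1, either library of leukemia 92 or either pro-B library.

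Signalling and survival lists gave no call. In MLL fusion targets 2 of 22 rose and 20 did not pass, 2 higher and 1 lower adjusted over the list alone (median 0.20, or 0.15 with genes at 0 at the floor, camera adjusted p = 0.063, against 0.0021 and 0.015 without leukemia 1 replicate 1 and leukemia 92 replicate 1, and 0.048 on the leukemia libraries alone). Bcl2, the survival gene, rose from 27.4 ± 4.30 to 63.3 ± 4.45 CPM, and it was also the 1 gene of 16 in the BCL2 family that passed, 3 higher and 2 lower adjusted over the list alone (median 0.04, mean -0.0079, test upward, camera adjusted p = 0.48). In ERK output 1 of 18 rose, Ccnd1, cyclin D1, from 300 ± 23.3 to 585 ± 32.3 CPM, and 17 did not pass, 3 and 3 adjusted over the list alone (median -0.04, mean -0.02, test upward, camera adjusted p = 0.74). Of 23 RAS pathway components edgeR called 0, with 5 higher at an unadjusted p under 0.05, 2 higher adjusted over the list alone and 3 higher by DESeq2 (median 0.06, camera adjusted p = 0.29). Among p53 targets 1 of 24 fell, Fas, the death receptor, by 1.84 on the log2 scale, and 23 did not pass, 3 lower adjusted over the list alone (median -0.02, camera adjusted p = 0.59). In immediate early and stress genes 2 of 24 fell and 22 did not pass, 3 lower adjusted over the list alone (median 0.04, mean -0.18, test downward, camera adjusted p = 0.59). That list was higher without leukemia 1 replicate 2 (median 0.24, adjusted p = 0.0047), and its median was -0.33 without replicate 1. Gadd45b, a stress response gene, fell from 72.8 ± 12.2 to 13.0 ± 0.957 CPM. Of 30 interferon response genes edgeR called 0, also adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05 and 1 and 2 by DESeq2. Their median was -0.45 (camera adjusted p = 0.59), against -0.998 with adjusted p = 0.023 without leukemia 92 replicate 1 and 0.80 without leukemia 1 replicate 2.

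The largest rises in leukemia 92, beside Brip1, were Krt75, a keratin, with a ratio of 3637 (95% interval 1006 to 30038), Sema5a, a semaphorin, with 2410 (432 to 95231), Rimkla (log2 change 6.73), Amph (5.83) and Ppm1j, a phosphatase (3.60). Rimkla was at 7.35 without leukemia 1 replicate 1. Among the largest falls were Xlr4c, an X-linked gene, with a ratio of 319 (109 to 1550), Filip1 (log2 change -6.45), Xlr4a (-6.20), H19, Lhx2 (-4.99) and Gnb4 (-4.79). Without leukemia 92 replicate 1 or 2, Filip1 was at -5.68 or -7.96 and Xlr4a at -5.52 or -7.36. Lhx2 was at -5.63 without leukemia 92 replicate 2. Reads of the Xlr4 paralogs cannot be assigned with certainty. Pro-B cells had 2.33 ± 0.425 CPM of Sema5a and 80.7 ± 6.73 CPM of Gnb4.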

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

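The tests of granulocyte RNA, of dilution, of NK cells, of plasmacytoid dendritic cells and of scaling were chosen after the results they address were seen, while the tests on transcript length and on the neighbours of Brip1 were set up before theirs. The test of scaling replaced an earlier one, on the median of all genes, whose outcome was fixed by centring.

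The leukemias differed in their change from the shared pro-B libraries, by the test of leukemia 92 against leukemia 1, for 2 of the genes named for leukemia against pro-B cells and for 8 lists, beside the 27 genes named for that test itself. Stfa3 was higher in leukemia 92 by 1.99 and Zbtb46 by 1.83 on the log2 scale. Median differences were -0.57 for ATR and CHK1 checkpoint genes, -0.53 for homologous recombination and Fanconi genes, -0.78 for replication, -0.68 for mitosis, -0.33 for ribosome biogenesis, 0.78 for mature B, -1.54 for plasma cell and -2.81 for T and NK genes. Without leukemia 1 replicate 2 the plasma cell median was -0.36 and the T and NK median -0.70. None of the 8 list differences passed camera with an estimated correlation, which had 2 lists at an unadjusted p under 0.05, while fry called 1 higher and 1 lower.

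Replicate 2 of leukemia 1 differed from replicate 1 more than the leukemias differed from each other. RNA of granulocytes and other non-leukemic cells may account for the genes higher in replicate 2, since the myeloid list had a median log2 ratio of 4.39, with 24 of 34 genes at least 4-fold higher, and Y-linked CPM was 9.06 times higher. B-lineage genes had a median log2 ratio of 0.31, which does not decide on simple dilution for the 104 genes at least 4-fold lower. Replicate 2 also held 4254 light-chain V segment counts against 102 in replicate 1, though fewer than the 7768 and 11638 of the pro-B libraries. B-lineage transcripts of other cells may therefore be part of that list's level. Loss of long transcripts is a candidate explanation for those: across 10216 genes the log2 ratio had a Spearman correlation of -0.37 with transcript length, against -0.10 and -0.03 in the other pairs, and -0.40 without genes at least 2-fold higher, a value added after the first was seen (genes are not independent replicates). A median length of 4828 bases for the lower genes, against 3449 for all, and the source of the male cells were not tested further, so a different animal, a different tumour share and RNA quality stay open.

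Both pro-B libraries held more transcripts of NK and plasmacytoid dendritic cells than the leukemia libraries, such as Gzma at 105 and 90.5 CPM and Siglech at 1369 and 1545 CPM. In a test of 20 such genes 14 were at least 4-fold higher in both pro-B libraries than in every leukemia library, and it was split after that was seen, into 80% of the 10 NK genes and 60% of the 10 plasmacytoid dendritic genes. These shares describe the pattern and do not decide whether NK or dendritic cells inside the B220+ CD43+ IgM- sort, or the pro-B cells themselves, carry the transcripts. A scaling factor moves all genes of a library alike, so by itself it cannot set these 20 genes apart from the others. In unscaled counts the median log2 ratio of the 20 genes minus that of all tested genes was -4.07 (quartiles -5.80 to -3.01 against -0.65 to 0.42). The 20 genes were picked for this pattern, so that gap describes it and is no independent test of scaling. Both pro-B libraries also held light-chain V segment counts, 7768 and 11638. Leukemia 1 replicate 2 had 4254, and the other leukemia libraries had 102 to 562. Igj stood at 141 and 173 CPM in the pro-B libraries and 107 CPM in leukemia 1 replicate 2. The source of all these transcripts stays open.

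Brip1 was 5.02 higher on the log2 scale in leukemia 92 than in leukemia 1. Gain of a region spanning its 10 nearest tested neighbours is argued against, since these had a median log2 difference of 0.057 (range -1.33 to 3.52). The top was Gm11477, a gene next to Brip1 in that order, at 1.36 CPM or less (edgeR adjusted p = 0.043). A median over 10 genes cannot decide on a gain of Brip1 alone or with 1 neighbour. An insertion of a retroviral vector near the gene could give such a rise and was not tested, since reads across a junction are not in a table of counts. Why the leukemias differ in Brip1 stays open.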

How the results depend on the processing

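No alternative here was chosen after the data were seen, but medians of exactly 0 were counted as not reversed after they had appeared (erythroid and platelet genes without leukemia 1 replicate 2 and MLL fusion targets without leukemia 92 replicate 2, both in the comparison of the leukemias). No called gene changed sign in any alternative that was run. DESeq2 size factors shared 98.1% of the calls of leukemia against pro-B cells and 98.5% of those between the leukemias. Values of 1 library below 0.111 to 0.140 CPM rest on fewer than 3 counts.

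For leukemia against pro-B cells DESeq2 called 2335 genes higher and 2434 lower, glmTreat 776 and 992, and the 3-group fit 2107 and 2605. Leaving out 1 library or leukemia gave 0 to 4893 higher and 0 to 5241 lower, and the cause was not tested. Camera with an estimated correlation called 0 lists higher and 0 lower. The number of called lists otherwise stayed within 1.5 times. Between the leukemias DESeq2 called 1322 higher and 1345 lower and glmTreat 46 and 44. The fit on the leukemia libraries alone called 0 and 0 (edgeR, 2366 at an unadjusted p under 0.05), with 2 lists higher, and the cause was not tested. Leaving out 1 library gave 0 to 3909 higher, 0 to 4224 lower and 1 to 3 lists higher. Camera with an estimated correlation called 0 and 0.

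The replicate numbers are shared between groups, so they were also fitted as a replicate block. Differences between replicates were not shared between groups (correlations across genes of -0.10, 0.08 and -0.03). With the replicate block 779 genes were higher and 1110 lower in leukemia, each library being a replicate. Between the leukemias it called 0 and 0 (edgeR, 3042 at an unadjusted p under 0.05), with fewer residual degrees of freedom.

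Some medians of uncalled lists near 0, or set by leukemia 1 replicate 2, reversed, and apart from that library the cause was not tested. For leukemia against pro-B cells, stem and progenitor genes were at -0.0036 per library, -0.41 with the block, -0.48 with 3 groups and -1.17 to 0.85 with samples left out, and stromal genes at -1.78 to 2.32. Between the leukemias without a filter the BCL2 family was at -0.077 and stem genes at -0.32, and with the block ERK output was at 0.024 and p53 targets at 0.037. With 1 library left out the medians ran from -0.086 to 0.25 for the BCL2 family, -0.23 to 0.59 for dendritic, -0.045 to 0.087 for ERK output, -0.17 to 0.60 for stem, -0.33 to 0.24 for immediate early, -0.998 to 0.80 for interferon, -3.32 to 1.70 for myeloid, -3.54 to 1.95 for stromal and -0.38 to 0.33 for p53 target genes.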

Other observations

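The genes of this paragraph and the next were chosen after their values were seen. Cdkn2a, the locus of p16 and p19ARF, stood at 59.0 ± 23.9 CPM in leukemia 1 and 97.3 ± 5.15 CPM in leukemia 92 (SD, n = 2 each) against 0.190 ± 0.00694 CPM in pro-B cells, a rise of 8.67 on the log2 scale (SE 0.49, edgeR adjusted p = 0.0083). Trp53 itself was level (log2 change 0.05, adjusted p = 0.77). Csf1r, the receptor of macrophage colony-stimulating factor, rose by 6.18 (SE 0.68, adjusted p = 0.017) and was present in all 4 leukemia libraries at 138 to 464 CPM. Cd14 stood at 704 ± 14.2 CPM in leukemia 92 and 27.9 ± 27.7 CPM in leukemia 1 (log2 difference 4.65, adjusted p = 0.066).

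A set of 36 tested genes was taken by symbol (Il, a number, then r, a or b), mostly interleukin receptors, without most interleukins. Of these 12 rose and 8 fell in leukemia, the same numbers with DESeq2 size factors. The falls included Il2rb, also among the NK genes above, at 116 and 136 CPM in the pro-B libraries. Of 8 Hoxa genes 7 fell, while of 6 Hoxb genes 1 rose (Hoxb7, at 1.37 to 11.6 CPM in the leukemia libraries and 1 count in pro-B cells) and 5 did not pass. Of 14 Klra genes 12 fell and 1 rose. All 6 stefin genes of the Stfa family rose, 5 with DESeq2 size factors. Shares of heavy-chain V segments are over the 37 that had an entry, and their intervals cover counting error alone. The most frequent segment, Ighv1-54, held 33.2% (95% interval 27.4% to 39.4%) of 253 reads and 33.6% (27.7% to 39.9%) of 247 reads in the libraries of leukemia 92. In leukemia 1 replicate 1 it was Ighv1-5 with 46.7% (41.6% to 51.9%), while in replicate 2 it was Ighv1-54 with 12.8% (64 of 500 reads). In the pro-B libraries the most frequent segments were Ighv9-3 with 13.7% (12.3% to 15.2%) and Ighv1-18 with 24.5% (23.1% to 25.9%).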
